A study of Mus musculus with 20 samples.

How the data were processed

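Total RNA from the lungs of male AKR/J mice, an inbred strain, was profiled on Illumina mouse bead arrays, on which each probe's signal is the mean brightness of many beads that carry it. There were 20 arrays, 1 per sample. Per the labels, lung tissue was excised into RNA stabilising solution, homogenised in Trizol and purified on columns, and the RNA was amplified and labelled with biotin. The labels put 7 arrays in room air (RA), 3 in room air with losartan (RA_Los), 7 in cigarette smoke (CS) and 3 in cigarette smoke with losartan (CS_Los). They also give a batch: batch 1 holds 3 arrays of each group and batch 2 holds 4 RA and 4 CS arrays. The labels number the CS_Los arrays 7 to 9 and the arrays of batch 2 from 1 to 4, and the text calls them CS_Los 1 to 3 and RA or CS 4 to 7 in that order. The labels number the samples as replicates and do not state in words that each came from a separate animal, so the p-values measure the spread between these samples.

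The deposited signals are probe intensities on a linear scale before normalization, per the file headers. The signals were summarised with BeadStudio, version not given, per the submitters' processing notes. Whether background was subtracted is not given in the sources used here, and 0 signals lay below zero. The deposited detection p-values compare each probe with the negative-control beads of its array, per the file headers. Each detection column was paired with the signal column that precedes it, as the layout of the deposited table gives it. A second deposited table holds log2 values by the authors. Set against the intensities, these equal the log2 signal shifted so that each array has a median of 8 (largest difference 0.0069), and the spread of the arrays was not equalised. They served as an alternative.

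The table held 25697 probes. Background was corrected with limma's nec function, which infers the mean and SD of the negative controls from the detection p-values (offset 16), followed by quantile normalization over all 20 arrays and log2. R 4.3.3 and limma 3.58.1 were used. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 17012 probes (66.2%). The platform annotation named 23141 probes with 1 gene symbol each and 0 probes with several. The other probes stayed unnamed. All 23141 matched the reference gene table, and 0 of the tested symbols needed updating. For each gene the kept probe with the highest mean signal was used, which gave 11196 named genes and 1523 unnamed probes, 12719 features in all. The probes of Agtr2 and Agt did not pass the detection filter, so these genes were not analysed here. No 2 arrays were identical (highest Spearman correlation between arrays 0.978).

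Smoke was compared with room air over the 14 RA and CS arrays with batch as a term, by limma's lmFit and eBayes. Losartan was given in batch 1 alone, so its comparisons used the 12 arrays of batch 1 with all 4 groups sharing one estimate of the spread. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. The interaction of losartan with smoke was fitted within batch 1, and that of smoke with batch over the RA and CS arrays. The smoke score of an array is the mean log2 signal of the genes higher in CS minus that of the genes lower in CS, with the genes taken from batch 2 alone (308 higher, 393 lower) and the score read in batch 1. This choice keeps the CS arrays that select the genes apart from those that are compared. Its differences were tested by an exact 2-sided permutation test (3 against 3, smallest possible p 0.1) and by limma's fry. The 37 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative, and adjusted over the lists of a comparison. Where a gene was detected on 0 arrays of a group, its change is given as "at least N-fold": the mean of the brighter group against, per array, the higher of the lowest detected signal and the gene's own.

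The designs, the gene lists and the alternatives were fixed before the data were examined. So was the rule for named genes: per comparison the 10 highest and 10 lowest log2 changes past the threshold, for CS against RA of the same sign within each batch and without predicted or clone symbols. Where fewer than 3 genes passed, the 5 highest and 5 lowest moderated statistics were taken as not past the threshold. To these were added up to 4 called members of each list and the genes of the study question, of which some are not reported here (the others were Agtr1a, Agtr1b, Agtr2, Ace, Agt, Tgfb1, Ccn2, Eln, Mmp9, Mmp12, Timp1, Cyp1a1, Nqo1, Gclc, Hmox1). The alternatives covered background correction, normalization, the series' own log2 values, probe filters, all kept probes, a fold minimum of 1.5, eBayes with trend and robust, arrayWeights, all 20 arrays, other treatments of batch, the replicate number as a block and leaving out each array. A fit with clock-gene components as covariates, which leaves the clock genes untested, was added after seeing the data. Values of single arrays in the text, and genes named because another setting called them, were chosen after their values were seen.

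The code was tested on simulated data made with the means and spreads of these arrays, with 100 of 12719 features changed by each size. In the CS against RA fit, 98 of 100 changes of 1 log2 unit and 43 of 100 changes of 0.5 were recovered, with 4 false calls. In the CS_Los against CS fit, 65 of 100 changes of 1 unit and 10 of 100 of 0.5 were recovered, with 2 false calls. In the losartan by smoke interaction, 25 of 100 and 1 of 100 were recovered. In the smoke by batch interaction, 39 of 100 and 1 of 100 were recovered. In the simulated list test for CS against RA, the 1 shifted list was found and 0 others were. The simulation used means and spreads and not the correlation of genes within a list. It therefore cannot tell how often correlated lists pass by chance at the preset correlation. On the real arrays the correlation estimated for CS against RA ranged from -0.037 (renin-angiotensin list) to 0.67 (cardiac and skeletal muscle list).

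The labels differ in places. The protocol text gives 6 to 7 weeks of smoke and speaks of 3 groups, while the series' design text gives 2 months and the 4 groups used here. Slide positions and scan dates were not used here. The number of arrays limits the precision of every comparison.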

Results

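Gene expression was measured in whole lung of male AKR/J mice that breathed room air or cigarette smoke, with or without losartan, a blocker of the angiotensin II type 1 receptor, in the drinking water (0.6 g/L). Mice were 6 to 8 weeks old at the start and were exposed to smoke for 2 h per day on 5 days per week, at an average carbon monoxide level of 350 ppm. The groups held 7 RA, 7 CS, 3 RA_Los and 3 CS_Los arrays. Signals differed between the batches. The median probe signal was 57.2 to 72.3 on the 12 arrays of batch 1 and 87.4 to 100.4 on the 8 arrays of batch 2, and the detected probes numbered 13946 to 15155 and 15089 to 15784. The first principal component of the normalized values carried 49.2% of the variance and separated the batches. The smoke comparison was therefore fitted with batch as a term. The gene counts, and the medians of the lists that passed in that fit, are also given within each batch. Most other list results are given from the joint fit only.

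The first comparison asked what smoke did to the lung. The highest changes among named genes included Retnla, Saa3, Cd177 and Scgb3a1. Retnla, a secreted protein of alternatively activated macrophages and airway epithelium, was 6.59-fold higher in CS than in RA (log2 change 2.72 ± 0.207, SE, n = 7 per group; adjusted p = 1.12e-06). Saa3, an acute phase protein, was 6.08-fold higher (2.60 ± 0.292; adjusted p = 3.23e-05), and the neutrophil surface protein gene Cd177 was 5.49-fold higher (2.46 ± 0.212; adjusted p = 3.01e-06). Scgb3a1, a secretoglobin of airway secretory cells, showed the highest log2 change, 3.14 ± 0.767 (adjusted p = 0.013), with a wide spread in each group (SD 1.67 in RA and 1.80 in CS). Tff2, a mucosal trefoil peptide, rose by 2.57. The secretory glycoprotein gene Gp2 was called higher (adjusted p = 0.0132) and was detected on 6 of 7 CS and 1 of 7 RA arrays, so no size is given for it. The acute phase gene Orm2 rose by 2.00.

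Of 16 measured neutrophil genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 change of 0.766 over the list. Besides Cd177, these included the granule protein gene Ltf (2.32), the iron-binding lipocalin gene Lcn2 (1.45) and the calcium-binding protein gene S100a9 (1.29 ± 0.197; adjusted p = 0.000496). The list differed from other genes by camera (adjusted p = 6.83e-10), though not past the threshold with the correlation estimated from the arrays (adjusted p = 0.0783 with an estimated correlation). Its median was 0.856 in batch 1 and 0.637 in batch 2. With clock covariates over all 20 arrays (described below) its mean stayed at 0.885 ± 0.25, from 0.88 ± 0.13, and did not pass (adjusted p = 0.13). The call of Ltf ended without RA 1, 3, 5, 6 or 7 or CS 2, 3 or 5 (adjusted p up to 0.0659). Chemokine and cytokine genes gave 7 higher and 1 lower of 38, among them the neutrophil attractants Cxcl5 (1.71 ± 0.251; adjusted p = 0.000352) and Cxcl1 (1.11 ± 0.23; adjusted p = 0.00453), or 8 and 1 adjusted over the list alone. That list as a whole did not pass (adjusted p = 0.0737). Monocyte and interstitial macrophage genes gave 5 higher and 0 lower of 14 (6 and 0 adjusted over the list alone), led by the chitinase-like gene Chil1 (1.17), the fractalkine receptor gene Cx3cr1 (1.17) and Plac8 (1.01). The list passed at the preset correlation (adjusted p = 0.0148) and not otherwise (adjusted p = 0.492 with an estimated correlation), with medians of 0.35 and 0.161 in batches 1 and 2. Its mean went from 0.336 ± 0.0816 to 0.137 ± 0.138 with the clock covariates (adjusted p = 0.553).

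Some members of the lymphocyte lists were also called. Of 15 B cell and plasma cell genes 8 rose and 0 fell (9 and 1 adjusted over the list alone), including the B cell receptor components Cd79a (1.11 ± 0.277; adjusted p = 0.0147) and Cd79b (0.98 ± 0.175; adjusted p = 0.00158). Of 24 T cell and NK cell genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them Cd8b1 (0.78) and Cd6 (0.77). By camera the adjusted p was 0.000357 for the B cell list and 0.000484 for the T cell list. Neither passed with the correlation estimated (adjusted p = 0.478 and adjusted p = 0.418 with an estimated correlation). The medians in batches 1 and 2 were 0.486 and 0.463 for B cell genes and 0.249 and 0.158 for T cell genes. A fit over all 20 arrays with the first 2 principal components of the circadian clock genes as covariates was chosen after seeing the data. The first component separated every CS array (0.259 or more) from every RA array (-0.739 or less). Here and below, this fit therefore cannot tell clock state from smoke. With it, the B cell and T cell list means differed in the other direction. The B cell mean went from 0.47 ± 0.179 to -0.298 ± 0.294 and the T cell mean from 0.259 ± 0.0831 to -0.0939 ± 0.134, neither past the threshold (adjusted p = 0.553 and adjusted p = 0.616). In the club and secretory airway list 7 of 22 members rose, among them Scgb3a1, Retnla, Tff2 and Ltf, and 1 fell (10 and 3 adjusted over the list alone). Its camera adjusted p was 0.00108 (adjusted p = 0.506 with an estimated correlation), with medians of 0.434 and 0.401 in batches 1 and 2. In batch 2 the list mean, against the RA mean, was 0.923 on RA 4 and between -0.422 and -0.161 on the other RA arrays, and 0.342, 1.27, -0.0607 and 1.82 on CS 4, 5, 6 and 7. The cardiac and skeletal muscle list stood at 1.16 on RA 4 and at -0.38, 1.45, -1.32 and 1.68 on the same CS arrays. In batch 1 the 2 lists went together less. On CS 1, 2 and 3 the club list stood at 1, 1.08 and 1.07 and the muscle list at 1.07, -0.0877 and -0.222. On RA 2 they stood at 0.398 and 1.16. Ciliated cell genes gave 2 higher of 18, Cyp2j9 (0.39) and Tubb4b (0.22), or 1 adjusted over the list alone. The list's adjusted p was 6.45e-05 (adjusted p = 0.492 with an estimated correlation), with medians of 0.433 and 0.237 in batches 1 and 2. With the clock covariates the means went from 0.931 ± 0.368 to 1.15 ± 0.763 for the club list and from 0.294 ± 0.136 to 0.697 ± 0.261 for the ciliated list, neither past the threshold (adjusted p = 0.37 and adjusted p = 0.347). The call of Tubb4b held in 3 of 14 fits with 1 array left out and ended in 8 of 15 other settings (adjusted p up to 0.646).

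**Figure D1:**
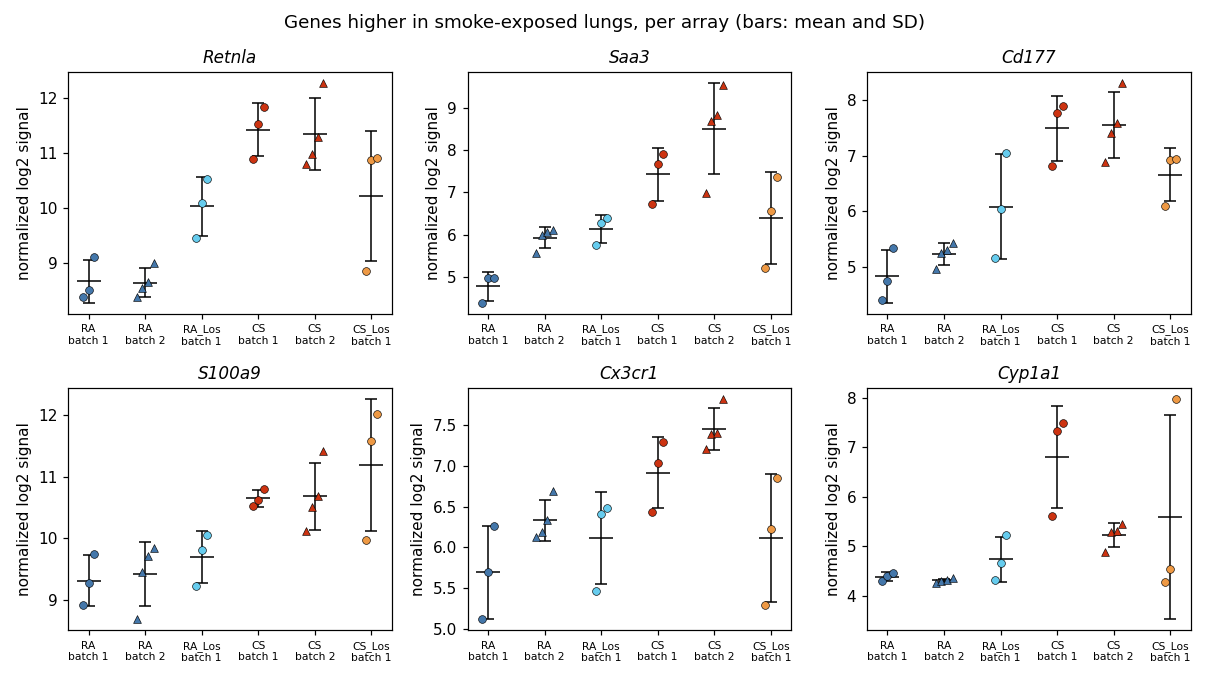
Normalized log2 signal (y axis) of 6 genes on each array, grouped by exposure and batch (x axis); circles are batch 1, triangles batch 2, and bars show the mean and SD. Retnla lies near 8.65 in RA and 11.37 in CS over both batches, while Cyp1a1 averages 6.80 in CS of batch 1 and 5.23 in CS of batch 2.

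Genes that respond to smoke chemicals gave a narrower picture. Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), was detected on 7 of 7 CS arrays and 0 of 7 RA arrays and was at least 1.97-fold higher (fitted log2 change 1.56 ± 0.279; adjusted p = 0.00158). It was at least 3.37-fold higher in batch 1 and at least 1.32-fold higher in batch 2. With RA at background in both batches, these are bounds, and no size of a difference between batches is given. Cyp1b1, another AhR target, rose by 0.85 ± 0.123 (adjusted p = 0.000297). These were the 2 called members of 12 in the AhR list, which gave 5 higher and 1 lower adjusted over the list alone and did not pass as a list (adjusted p = 0.0576). Against the RA mean of its batch, the list stood at 0.285 to 0.551 on the CS arrays of batch 1. On those of batch 2 it stood at 0.0333 to 0.35. Of 31 antioxidant genes of the transcription factor NRF2, 4 rose and 0 fell (6 and 2 adjusted over the list alone). They were the cystine transporter gene Slc7a11 (at least 1.13-fold; adjusted p = 0.000292), Cbr3 (0.43), Tkt (0.37) and Cbr1 (0.33). The calls of Cbr3, Tkt and Cbr1 ended in 10, 7 and 6 of 14 fits with 1 array left out. The list's adjusted p was 0.0328 (adjusted p = 0.492 with an estimated correlation). Its median was 0.15 in batch 1 and 0.117 in batch 2, where it did not pass (adjusted p = 0.243). Over both batches the median was 0.0714, and it was 0.0389 under 75th percentile centring and 0.0429 with the authors' log2 values. Nqo1 (0.33; adjusted p = 0.0785), Gclc (-0.12) and Hmox1 (0.06) were not past the threshold. With the clock covariates the list means went from 0.287 ± 0.0701 to 0.283 ± 0.15 for AhR targets and from 0.102 ± 0.0481 to 0.133 ± 0.0921 for NRF2 genes (adjusted p = 0.366 and adjusted p = 0.389).

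Most genes of the heat shock and unfolded protein response were lower in smoke-exposed lungs in this fit. Of 27 measured members 18 fell and 1 rose (20 and 1 adjusted over the list alone), with a median log2 change of -0.567. Hspa1a, an inducible heat shock protein gene, fell by 4.24 ± 0.358 (adjusted p = 2.97e-06), from a mean log2 signal of 10.94 ± 0.837 (SD, n = 7) to 6.71 ± 0.795 (SD, n = 7). The cochaperone and small heat shock protein genes Hsph1 (-2.46), Hspb1 (-1.83) and Dnajb1 (-1.62) fell with it. The list passed at the preset (adjusted p = 1.46e-17) and at the estimated correlation (adjusted p = 0.0157 with an estimated correlation). Its median was -0.476 in batch 1 and -0.604 in batch 2. With the clock covariates over all 20 arrays the list mean turned from -0.773 ± 0.134 to 0.0686 ± 0.0877 (adjusted p = 0.597). Hspa1a (0.06), Hsph1 (0.56), Hspb1 (0.63) and Dnajb1 (0.03) turned positive as well, none past the threshold.

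Genes induced by glucocorticoids were lower as well: of 15 measured 12 fell and 1 rose, over all genes and adjusted over the list alone. Tsc22d3, the glucocorticoid-induced leucine zipper, fell by 1.61 ± 0.148 (adjusted p = 4.83e-06). The cell cycle inhibitor gene Cdkn1a (-1.67), Angptl4 (-1.60) and the clock gene Per1 (-1.50) fell too. The list passed at both settings of the correlation (adjusted p = 6.04e-10; adjusted p = 0.0414 with an estimated correlation), with a median of -0.783 in batch 1 and -0.901 in batch 2. With the clock covariates the mean of its 14 members other than Per1 turned from -0.716 ± 0.142 to 0.108 ± 0.145 (adjusted p = 0.607). Of 17 immediate early genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), among the former Fos (-1.18), Klf2 (-0.84) and Klf4 (-0.78). The list's adjusted p was 0.0159 (adjusted p = 0.529 with an estimated correlation). Its median was -0.225 in batch 1 and -0.19 in batch 2, where it did not pass (adjusted p = 0.0834). Its mean turned from -0.277 ± 0.152 to 0.444 ± 0.216 with the clock covariates (adjusted p = 0.366).

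Circadian clock genes moved in both directions. Of 16 measured 3 rose and 5 fell. The clock output gene Dbp rose by 2.60 ± 0.269 (adjusted p = 1.49e-05) and the clock repressor gene Nr1d1 by 2.17 ± 0.102 (adjusted p = 3.37e-09), while Per2 fell by 1.60 ± 0.286 (adjusted p = 0.00163). As a list they did not pass (adjusted p = 0.535), as members went opposite ways. Clock genes also differed within groups: in batch 1, Dbp was 11.91 on RA_Los 2 and 12.51 on RA_Los 3, against 8.97 on RA_Los 1, and Hspa1a was 8.48 and 7.17 against 11.57 on the same arrays. With the first 2 components of the clock list as covariates over all 20 arrays, 3 genes were called between CS and RA and 0 of the 1631 above were among them. Of the called genes, 1623 are not clock genes. Their median change in the called direction went from 0.411 to 0.0186 and their median SE from 0.125 to 0.199. The change stayed at least 50% as large in 401 of them and had the opposite sign in 772. The 3 genes were Grap (-1.05 ± 0.168), Nppb (1.98 ± 0.275) and Ptges3l (1.21 ± 0.203). The first component lay at 0.259 or more on all CS arrays and at -0.739 or less on all RA arrays. The fit thus takes out differences that go with smoke as well as with the clock. The lost calls and turned signs cannot tell these apart.

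**Figure D2:**
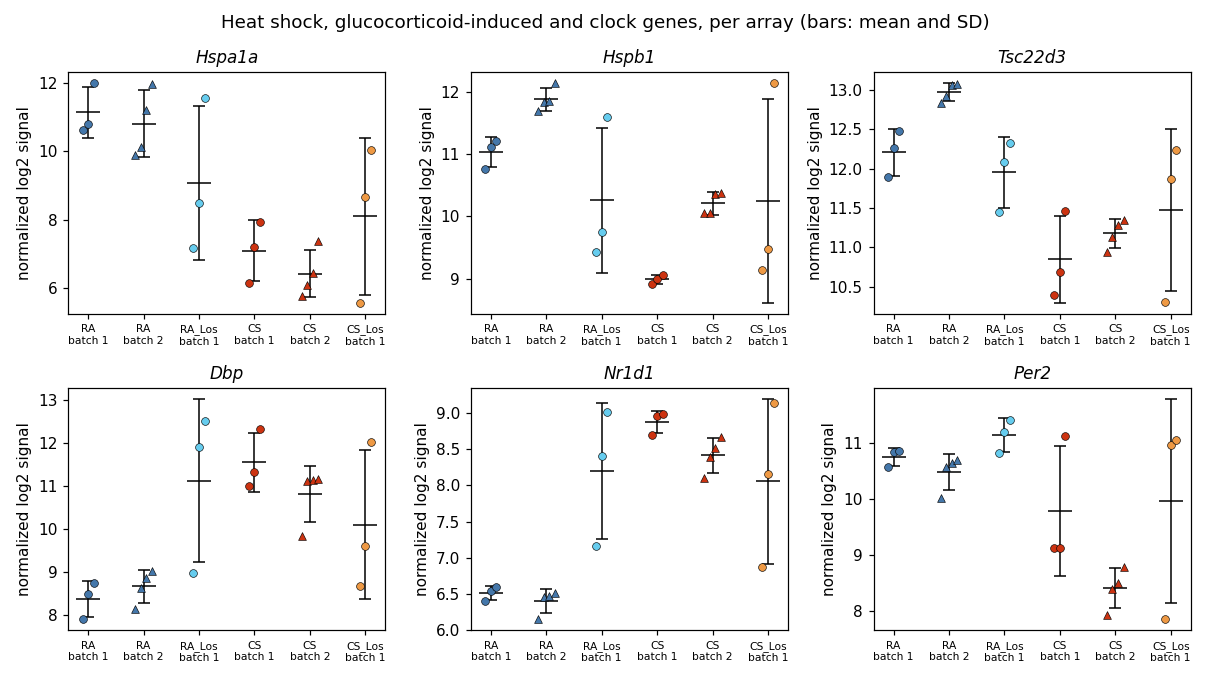
Normalized log2 signal (y axis) of heat shock, glucocorticoid-induced and clock genes on each array, grouped by exposure and batch (x axis); circles are batch 1, triangles batch 2, and bars show the mean and SD. Hspa1a averages 11.14 in RA and 7.09 in CS of batch 1, while the 3 RA_Los arrays range from 7.17 to 11.57 and the 3 CS_Los arrays from 5.57 to 10.05.

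For the genes of the study question, Mmp9, a gelatinase of neutrophils and macrophages, rose by 0.90 ± 0.18 (adjusted p = 0.00346). The macrophage elastase gene Mmp12 rose by 0.33 ± 0.0962 (adjusted p = 0.0352) and Eln, which encodes elastin, fell by 0.53 ± 0.151 (adjusted p = 0.0296). The call of Mmp12 ended without RA 1, 2, 4 or 6 or CS 3, 4, 6 or 7 (adjusted p up to 0.0757), and that of Eln without RA 1, 3 or 6 or CS 4 (adjusted p up to 0.0654). Elastic fibre genes gave 0 higher and 3 lower of 17 (1 and 4 adjusted over the list alone). The 3 were Eln, the crosslinking enzyme gene Lox (-0.78) and Adamtsl4 (-0.73), and the list did not pass (adjusted p = 0.269). The TGF-beta list gave 5 higher and 5 lower of 33 (6 and 9 adjusted over the list alone, list adjusted p = 0.955), with Tgfb2 (0.48) and Id2 (0.54) higher and Thbs1 (-0.46) lower. Tgfb1 (0.02 ± 0.0903; adjusted p = 0.919), Ccn2 (-0.24; adjusted p = 0.057) and Timp1 (0.17) were not past the threshold. None of the 10 measured genes of the renin-angiotensin list was called: Agtr1a, the receptor losartan blocks, was at 0.23 ± 0.111 (adjusted p = 0.187), and Ace at -0.12. Agtr1b was detected on 2 of 7 CS and 1 of 7 RA arrays. Collagen and matrix genes gave 0 calls of 24.

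Among markers of other cells in the tissue, erythroid genes gave calls, while muscle and mesothelial genes gave 0. Over all features 1631 of 12719 were called. Of 8 erythroid genes 3 fell and 0 rose (4 and 1 adjusted over the list alone): the haemoglobin gene Hbb-b2 (-1.87; adjusted p = 0.0208), the haem synthesis gene Alas2 (-1.69; adjusted p = 0.0298) and Slc4a1, detected on 0 of 7 CS arrays and at least 1.37-fold lower. A further haemoglobin gene, Hbb-bt, fell by 1.98. The call of Alas2 ended without RA 1, 2, 5 or 6 or CS 2, 3, 5 or 7 (adjusted p up to 0.0676). The erythroid list did not pass (adjusted p = 0.196), and its mean turned from -0.722 ± 0.279 to 0.43 ± 0.458 with the clock covariates. Cardiac and skeletal muscle genes gave 0 calls of 24 (list adjusted p = 0.16) and mesothelial genes 0 of 13 (list adjusted p = 0.297).

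In all, limma called 1631 of 12719 features between CS and RA, 775 higher and 856 lower, and 353 of them differed by at least 1.5-fold. All but 1 (1630) had the same sign within each batch, which a selection by the fit over both batches itself favours. Batch 1 alone gave 83 calls (3 against 3) and batch 2 alone 701 (4 against 4), and 672 of the latter (95.9%) had the same sign in batch 1. Called in both batches alone, in the same direction, were 59 features. Across genes, which are not independent replicates, the changes of the 2 batches correlated with Pearson's r = 0.69. The smoke effect differed between batches for 2 genes by the interaction test. The antimicrobial lectin gene Reg3b averaged 6.21 ± 0.367 (SD, n = 3) in RA of batch 1, against 4.50 ± 0.0724 in CS of that batch and 4.33 and 4.34 in RA and CS of batch 2 (interaction 1.72 ± 0.189; adjusted p = 0.00197). Its tested probe was detected on those 3 RA arrays alone, so the fitted 1.72 compares them with signals at background. Katnal1, related to a microtubule-severing enzyme, was higher in CS by 0.56 in batch 1 and lower by -0.47 in batch 2 (interaction -1.03 ± 0.15; adjusted p = 0.0326). Katnal1 kept its call in 3 of 14 fits with 1 array left out, those without RA 1, CS 2 or CS 6. As lists, 2 differed between batches at the preset correlation. For cholesterol and fatty acid synthesis genes (adjusted p = 0.000255; adjusted p = 0.845 with an estimated correlation) the median was -0.0265 in batch 1 and 0.134 in batch 2. For circadian clock genes (adjusted p = 0.0234; adjusted p = 0.766 with an estimated correlation) it was 0.0355 and -0.175.

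**Figure D3:**
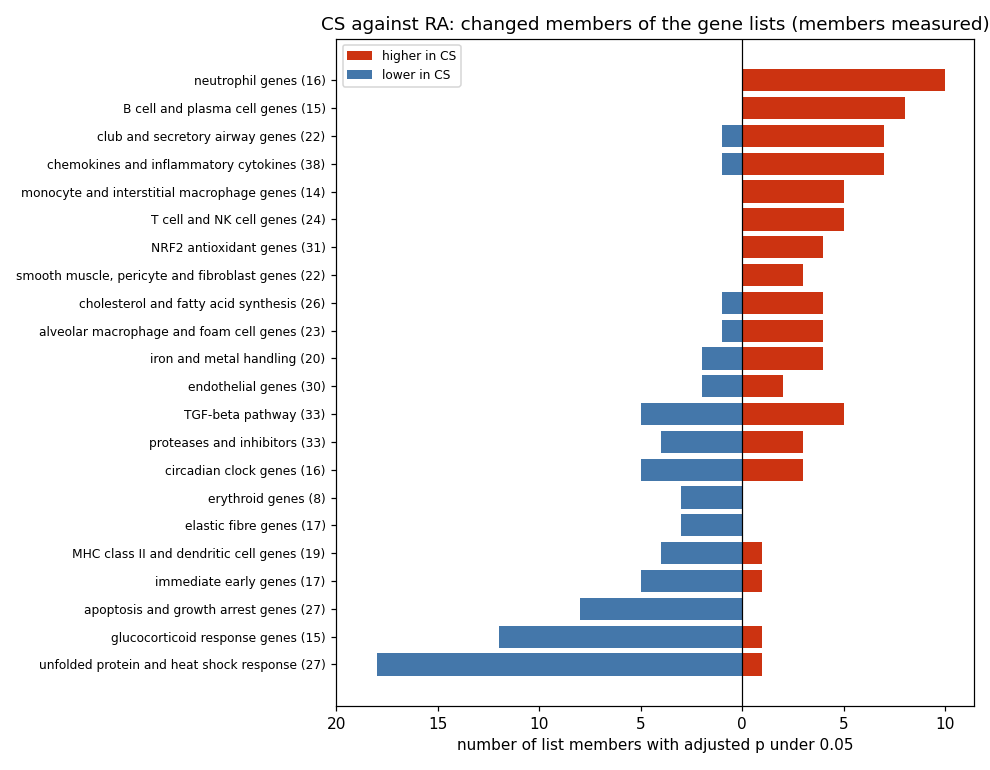
Number of members of each gene list (y axis, measured members in brackets) that were called higher (right) or lower (left) in CS than in RA (x axis, count); lists with at least 3 called members are drawn. The heat shock list has 18 members lower and the neutrophil list 10 members higher.

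The next comparison asked whether losartan changed the lung of smoke-exposed mice. No gene was called between CS_Los and CS by limma (3 against 3; 756 features had an unadjusted p under 0.05, where chance alone gives 636; smallest adjusted p = 0.556). The highest moderated statistics, none past the threshold, belonged to the chemokine gene Ccl9 (0.96 ± 0.197) and the cytokine receptor subunit gene Csf2rb2 (1.04 ± 0.218), and the lowest to Katnal1 (-1.10 ± 0.195) and the collagen receptor gene Mrc2 (-0.76 ± 0.142). In a fit over all 20 arrays Mrc2 alone was called (-0.75 ± 0.103; adjusted p = 0.00516). For the genes of the study question, Cyp1a1 stood at a fitted -1.21 ± 0.764, Eln at 0.58 ± 0.341, Tgfb1 at 0.30 ± 0.201, Agtr1a at -0.04 ± 0.185, Mmp9 at 0.23 ± 0.223 and Mmp12 at -0.07 ± 0.177, each with an adjusted p of at least 0.88. Ace stood at -0.74 ± 0.282 (adjusted p = 0.734). Cyp1a1 was detected on 1 of 3 CS_Los arrays (7.97 on CS_Los 1, against 4.27 and 4.54 on CS_Los 2 and 3) and on 3 of 3 CS arrays. As lists, alveolar macrophage genes (median 0.254), heat shock genes (0.405) and glucocorticoid response genes (0.350) were higher in CS_Los at the preset correlation, with adjusted p of 1.32e-06, 1.32e-06 and 0.00815. None of these 3 passed otherwise (adjusted p = 0.434, 0.434 and 0.547 with an estimated correlation). Adipocyte genes and MHC class II and dendritic cell genes also passed at the preset correlation (adjusted p = 0.0202 and adjusted p = 0.0365) and not otherwise (adjusted p = 0.434 and 0.547 with an estimated correlation). On CS_Los 1, 2 and 3 the heat shock list stood at -0.838, 0.224 and -0.357 against the RA mean, and on the CS arrays of batch 1 between -0.901 and -0.566. The glucocorticoid list stood at -0.917, 0.26 and -0.197 on these CS_Los arrays, and between -0.816 and -0.539 on CS. In these 2 lists CS_Los 1 was thus within or below the CS values and CS_Los 2 above the RA mean. The alveolar macrophage list stood at 0.523, 0.213 and 0.232 on CS_Los 1, 2 and 3. On CS 1, 2 and 3 it stood at -0.112, -0.0403 and 0.132, below each CS_Los array, and on RA_Los 2 at 0.296.

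The smoke score summarised the 701 genes called between CS and RA in batch 2. Whether smoke itself set these differences was not tested, and the score did not follow exposure on every array. It was -0.184 on RA_Los 3, which had no smoke, and -0.295 on CS_Los 3. In batch 1 it averaged -0.861 ± 0.065 (SD, n = 3) in RA and 0.195 ± 0.288 in CS, a difference of 1.06 (exact permutation p = 0.1, the smallest possible; fry p = 0.0228). In CS_Los it averaged -0.290 ± 0.756, which is -0.486 against CS, or -46% of the CS minus RA difference. This was within the spread between arrays (exact permutation p = 0.4, adjusted over the 5 score comparisons 0.5; fry p = 0.239). The 3 CS_Los arrays lay far apart: 0.468, -1.04 and -0.295. Without CS_Los replicate 2 the difference was -0.109 (exact permutation p = 0.7; fry p = 0.758). Without CS_Los replicate 1 it was -0.865 and passed fry (p = 0.0205; exact permutation p = 0.1, the smallest possible). RA_Los averaged -0.469 ± 0.394, which is 0.392 above RA (exact permutation p = 0.3), and CS_Los minus RA_Los was 0.178 (exact permutation p = 0.9).

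**Figure D4:**
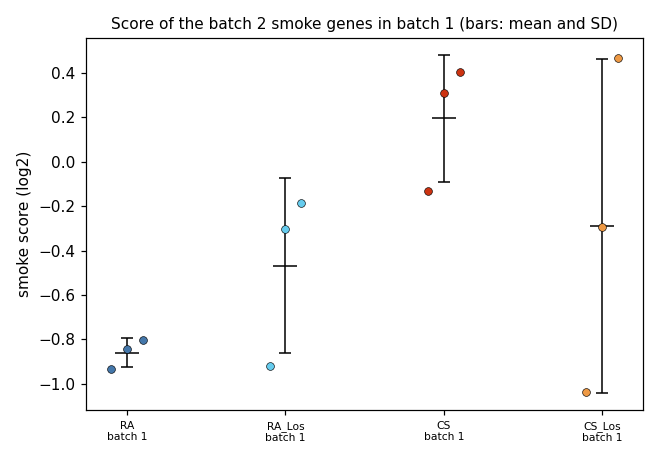
Smoke score (y axis, difference of mean log2 signals) of each batch 1 array by group (x axis); bars show the mean and SD. The RA arrays lie between -0.932 and -0.805 and the CS arrays between -0.132 and 0.407, while the CS_Los arrays range from -1.04 to 0.468.

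Losartan in room air was the control for the drug alone. One gene, Reg3b, was called between RA_Los and RA, at least 2.42-fold lower on its tested probe (fitted log2 change -1.61 ± 0.2; adjusted p = 0.0261). That probe was detected on 3 of 3 RA and 0 of 3 RA_Los arrays, and the gene's other probe on 1 of 3 RA_Los arrays. As given above, the tested probe was at background on all other arrays too, untreated RA of batch 2 among them. The call thus sets the batch 1 RA arrays apart and by itself shows no effect of the drug. In all, 606 features had an unadjusted p under 0.05. Reg3b kept the call in 2 of 12 fits with 1 array left out, those without RA 2 or RA_Los 1. It lost it with 4 other background or scaling settings. The neutrophil attractant gene Cxcl1 (1.78 ± 0.304; adjusted p = 0.24, but 0.0221 without RA_Los 3) and Eln (-1.11 ± 0.341; adjusted p = 0.964) were not past the threshold. At the preset correlation 15 lists passed and 0 did with an estimated correlation. The club and secretory airway list led them (median 0.729; adjusted p = 2.36e-07; adjusted p = 0.345 with an estimated correlation), and the circadian clock list was among them (median 0.525; adjusted p = 0.0137; adjusted p = 0.474 with an estimated correlation). The cardiac and skeletal muscle list also passed (median 0.376; adjusted p = 0.0372; adjusted p = 0.758 with an estimated correlation). Against the RA mean, the club list stood at 1.28, 1.89 and -0.168 on RA_Los 1, 2 and 3, and the cardiac and skeletal muscle list at 2.2, 1.25 and -1.99.

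Smoke with losartan was also set against each room air group. Between CS_Los and RA_Los 0 genes were called (680 at an unadjusted p under 0.05). Neutrophil genes had a median of 0.561 there, with 5 of 16 higher when adjusted over the list alone (S100a8, S100a9, Retnlg, Mmp8 and Clec4d) and 0 over all genes (list adjusted p = 1.92e-08; adjusted p = 0.187 with an estimated correlation). Retnlg, a neutrophil-expressed resistin-like gene, stood at 1.59 ± 0.351 (adjusted p = 0.679). Between CS_Los and RA, Reg3b alone was called (at least 2.35-fold lower, fitted log2 change -1.91 ± 0.2, adjusted p = 0.00402), and 829 features had an unadjusted p under 0.05. This call too rests on the batch 1 RA arrays, the only ones where the tested Reg3b probe was detected. Without CS_Los 3 there were 5 calls, the others being S100a9, Cd33, Retnlg and Klra17. The neutrophil list was higher in CS_Los than in RA at both settings (median 1.25, adjusted p = 4.62e-15, and adjusted p = 0.0345 with an estimated correlation), with 11 of 16 members higher when adjusted over the list alone. It was not the only list to move at the preset correlation. By camera 19 lists passed there between CS_Los and RA and 9 between CS_Los and RA_Los. With an estimated correlation 1 and 0 did. RA enters both this comparison and the preceding ones, so their values share chance.

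The last test asked whether losartan changed the smoke effect itself. By the interaction of losartan and smoke, limma called 0 genes (912 at an unadjusted p under 0.05; smallest adjusted p = 0.517). Eln stood at 1.69 ± 0.482 (adjusted p = 0.542) and Nqo1 at -0.62 ± 0.309 (adjusted p = 0.715). No size is given for Cyp1a1, which was at background on all RA arrays. At the preset correlation 8 lists passed, led by heat shock genes (median 0.608; adjusted p = 2.46e-06; adjusted p = 0.579 with an estimated correlation) and ciliated cell genes (-0.498; adjusted p = 0.000228; adjusted p = 0.579 with an estimated correlation). With an estimated correlation 0 passed.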

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

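Within the RA and CS groups (7 arrays each), 1 array stood apart from the other 6 by the gap to its neighbour in 22 of 294 checks of named genes, lists and the smoke score (7.48%; chance gives about 5%). Of these, 12 fell on CS 1, and they share genes, so they are not independent. The number given with each is the gap divided by the range of the group.

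On CS 1, heat shock and clock values were high: Hsph1 0.669, Per2 0.627, the heat shock list 0.617 and the clock list 0.675. Nos3 was high as well (0.674). Low on CS 1 were Lcn2 (0.577), the smoke score (0.629, at -0.132 against 0.311 or more on the other CS arrays), the alveolar type II list (0.87), the cholesterol and fatty acid list (0.738), the protease list (0.667), Sqle (0.669) and Elovl1 (0.72). Among the other CS arrays, Scgb3a1 was low on CS 6 (0.575), Mmp12 low on CS 5 (0.801) and Agtr1a high on CS 2 (0.605). Among RA arrays, Gp2 was high on RA 4 (0.745), Cyp2b10 and Per2 low on RA 7 (0.661 and 0.658), Cd163 low and Agtr1b high on RA 3 (0.697 and 0.675), elastic fibre genes high on RA 6 (0.68) and mesothelial genes high on RA 5 (0.679). Leaving out CS 1 gave 1918 called genes between CS and RA.

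The smoke effect differed between batches for 2 genes by the interaction test: 1.72 for Reg3b, whose signal was raised on the 3 RA arrays of batch 1 (5.89 to 6.61, and at most 4.96 on the other 17 arrays, where its tested probe was not detected), and -1.03 for Katnal1. Other assignments of smoke within each batch gave 2 or more such genes in 8 of 100 draws, the real one included, and 725 at the highest. A draw that reverses smoke in 1 batch puts the smoke effect itself into this interaction, so the draws do not test whether the count of 2 arose by chance.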

How the results depend on the processing

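The fit with clock components and its values were chosen after seeing the data, and its first component separates all CS from all RA arrays. All other settings were set beforehand. The 1631 genes called between CS and RA ranged from 1422 to 2035 under other background, scaling, filter, probe, spread, array weight and random batch settings. The count moved further in fits with other arrays or terms: 353 with a 1.5-fold minimum, 745 with all 20 arrays in a shared fit, 439 with batch left out, 83 in batch 1 and 701 in batch 2 alone (fewer arrays), and 3 with clock components. Leaving out each array gave 1194 (without RA 5) to 1918 (without CS 1). Of the 100 named genes called there, 77 kept their call with any 1 array left out. The counts for CS_Los against CS and CS_Los against RA_Los stayed at 0, with any array left out too, except for 1 each with all 20 arrays and 2 (Mrc2 and Ccl6) and 3 (Lima1 and 2 unnamed probes) with clock components. The 1 gene with all 20 arrays was Mrc2 and Lima1 in turn. Under RA_Los against RA, Reg3b lost its call (0 genes) with normexp on the signals alone, without background correction, under 75th percentile centring, with the authors' log2 values, without the probe filter and with all 20 arrays; clock components gave 3 others (Tecrl, Nppb and Abra). Leaving out arrays gave 0 to 1, and the gene without RA_Los 3 was Cxcl1. CS_Los against RA gave 0 under 75th percentile centring and the authors' values, 2 with arrayWeights, 16 with all 20 arrays, 23 with clock components and 1 to 5 with 1 array left out. The losartan by smoke interaction gave 0 in every setting run. The 2 genes of the smoke by batch interaction became 0 with normexp, without background correction, under 75th percentile centring and with the authors' values, 1 with all kept probes, with trend and robust and with all 20 arrays, and 1 to 3 with 1 array left out. Reg3b was called in each fit with 1 array left out, and Cyp1a1, whose RA signals were at background, joined it without CS 1. The smoke score difference between CS_Los and CS (-0.486) kept its sign in all settings, with the replicates left out from -0.865 to -0.109. Without CS_Los replicate 1 (-0.865) it passed limma's fry at 0.0205 (exact permutation p = 0.1, the smallest possible), and without any other array it did not. With all 20 arrays it was -0.553 and passed limma's fry at 0.0487 (the exact permutation tests were run in batch 1 alone), where the CS group then includes the batch 2 arrays that chose the genes. The cause of the other moves was not tested. Under the clock components, 50 named genes of CS against RA changed sign, 0 of them past the threshold in that fit (log2 changes): Hspa1a 0.064, Hsph1 0.56, Hbb-bt 0.47, Hbb-b2 0.69, Hspb1 0.63, Alas2 1.41, Dnajb1 0.028, Cyp1a1 -0.47, Tkt -0.13, Cbr1 -0.00691, Ces1f 0.57, Id2 -0.12, Tgfb2 -0.38, Lox 0.70, Adamtsl4 0.31, Eln 0.16, Timp3 0.28, Trem2 -0.23, Gpnmb -0.046, Ccl6 -0.48, Cx3cr1 -0.19, Oas2 0.52, Itgae 0.076, Ccl17 0.35, Ccr7 -0.027, Cd79a -0.89, Cd79b -0.48, Pou2af1 -0.50, Cxcr5 -0.67, Cd8b1 -0.41, Cd6 -0.69, Hc 0.083, Elovl1 -0.23, Cyp2j9 -0.1, Aplnr -0.38, Emcn -0.42, Nos3 0.26, Wnt2 -0.48, Meox2 -0.12, Mcm6 -0.013, Sqle -0.099, Hsd17b7 -0.41, Stard4 -0.054, Fos 1.16, Dusp1 0.34, Angptl4 0.0074, Lipe 0.065, Slc4a1 0.90, Cd163 0.78, Mmp12 -0.10. Slides were not given in the files used, so slide as a block was not run. Signal over background limits the dimmest genes, such as Cyp1a1 and Slc7a11 in RA, to bounds.

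The replicate numbers of the labels were checked for pairing in RA, RA_Los and CS. Of 13 pairs of arrays with the same number within a batch, 3 had deviations that correlated above 0.1 (mean -0.017). These were RA 2 with RA_Los 2 (0.31), RA 3 with RA_Los 3 (0.25) and RA_Los 1 with CS 1 (0.12), and the lowest was RA 5 with CS 5 (-0.34). Of 17 arrays 7 correlated best with their own number. All 7 were in batch 1, the batch of the losartan comparisons, as were the 3 pairs above 0.1. The same-number pairs of batch 2 all correlated below 0 (-0.28, -0.34, -0.13 and -0.054). No chance rate was worked out for this check, so whether the numbers mark a pairing stays open. The labels number the CS_Los arrays 7 to 9, and the numbers 1 to 3 used for them here were assigned in that order, so the block pairs them with other groups only by that choice. With the replicate block, CS against RA gave 1333 genes, the smoke by batch interaction 1, RA_Los against RA 1 and CS_Los against RA 1, and the other losartan counts stayed at 0.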

Other observations

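Single genes were also called in lists that did not pass as lists between CS and RA. Iron and metal handling genes gave 4 higher and 2 lower of 20 (5 and 2 adjusted over the list alone, list adjusted p = 0.085), with the iron exporter gene Slc40a1 (1.01 ± 0.0881; adjusted p = 3.01e-06) and the ferroxidase gene Cp (0.93 ± 0.143) higher and the haemoglobin scavenger receptor gene Cd163 (-0.63) lower, a call that ended in 11 of 14 fits with 1 array left out. Genes of apoptosis and growth arrest gave 0 higher and 8 lower of 27 (3 and 9 adjusted over the list alone, list adjusted p = 0.0701), among them Ddit4 (-1.04), Ddit3 (-0.89) and Mcl1 (-0.60). Alveolar macrophage genes gave 4 higher and 1 lower of 23 (adjusted p = 0.693), with the lipid-handling receptor gene Trem2 (0.54) and Gpnmb (0.47) higher. Dendritic cell genes gave 1 higher and 4 lower of 19 (3 and 4 adjusted over the list alone, list adjusted p = 0.157): Itgae (-0.67), Cd209a (-0.63) and Ccl17 (-0.54) fell and Ccr7 (0.47) rose. In the protease list 3 rose and 4 fell of 33, with a list adjusted p of 0.913 and the alpha-1-antitrypsin genes Serpina1b (-1.13 ± 0.194; adjusted p = 0.00124) and Serpina1a (adjusted p = 0.000635) lower.

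Structural cell lists did not pass as lists. Endothelial genes gave 2 higher and 2 lower of 30, with the apelin receptor gene Aplnr (0.72) higher and Nos3 (-0.49), whose call ended in 9 of 14 such fits, lower. Smooth muscle, pericyte and fibroblast genes gave 3 higher of 22, led by Wnt2 (0.65). Alveolar type II genes gave 1 higher and 1 lower of 22 and type I genes 1 lower of 14. Xenobiotic cytochromes gave 2 lower of 17, cholesterol genes 4 higher and 1 lower of 26, lipid export genes 1 and 1 of 23, adipocyte genes 2 lower of 11 and cell cycle genes 1 higher of 25. Interferon-stimulated genes gave 1 lower of 26, Oas2 (-0.68), and thymus genes 0 of 4. Oxidative phosphorylation genes gave 0 calls of 33 but a list adjusted p of 0.0219 (adjusted p = 0.822 with an estimated correlation). Their median was 0.112 in batch 1 and 0.0813 in batch 2, where the list did not pass (adjusted p = 0.0976). It depended on the scaling: 0.0861 over both batches, but 0.0151 under 75th percentile centring and 0.03 with the authors' log2 values.

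The fit with clock components was chosen after seeing the data, for the heat shock, glucocorticoid and neutrophil genes and for the CS_Los against CS count, and so were the tests of smoke with losartan and of blood. The counts over splits and the fits with 1 array left out were set beforehand. The bound for smoke alone was widened from 1 to 2 standard errors after its value was seen, and under the first bound that value would have counted against smoke alone. A test for a swapped label of CS_Los 2 was dropped after its value was seen, since a single array decides nothing. That value was a neutrophil mean of 8.94 on CS_Los 2, against 8.27 on the highest RA or RA_Los array of batch 1 and 8.25 on the lowest other smoke-exposed array of batch 1. For the CS_Los against CS count, the bounds set beforehand (fewer than 5 and at most 5 calls) were met, and the limit of detection was weighed against them only after the counts were seen.

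One hypothesis is that the clock state of the lung, as collection at another time of day would set it, accounts for the lower heat shock and glucocorticoid response genes in CS. Over all 20 arrays, the mean of the 29 members called lower, without the clock gene Per1, differed by -1.08 ± 0.183 (SE) between CS and RA. With the first 2 components of the 16 clock genes (57% and 35.4% of their variance) as covariates it differed by 0.0964 ± 0.0813. The difference shrank, and its error did not grow. These 29 were picked for being lower in CS on the same arrays, which inflates their difference, also the batch 1 value below. Without the clock components the whole heat shock list differed by -0.773 ± 0.134 and the glucocorticoid list without Per1 by -0.716 ± 0.142. However, in both batches the first component lay at 0.259 or more on every CS array and at -0.739 or less on every RA array. In batch 2 the second component lay at 1.41 to 2.46 on the CS arrays and at -2.11 to -1.11 on the RA arrays. The components thus stand for smoke as well as for the clock, and Per1 is among the 16 clock genes. Only on the losartan arrays did the first component not follow smoke. It lay at -2.09, 3.24 and 3.85 on RA_Los 1, 2 and 3, and at -1.44, -3.15 and 3.65 on CS_Los 1, 2 and 3. The shrinkage therefore cannot tell clock state from smoke. Smoke alone could not be told apart from this: CS_Los minus RA_Los was -0.105 ± 0.376, against -1.07 for CS minus RA in batch 1, and 2 SE below it reach past 50% of that value. Whether smoke itself shifts the clock stays open and untested, since in batch 2 every CS array differs from every RA array in Nr1d1 and Per2, and collection times were not used here.

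Another hypothesis is that the rise of neutrophil genes is separate from the clock. The mean of the 10 called neutrophil genes, of which 3 (Ltf, Mmp9 and Lcn2) also stand in other lists, differed by 1.29 ± 0.176 between CS and RA. With the clock components it differed by 1.21 ± 0.354. These 10 were picked for being higher in CS on the same arrays, which inflates their mean. Over all 16 measured members the mean went from 0.88 ± 0.13 to 0.885 ± 0.25 and did not pass (adjusted p = 0.13). The difference thus did not shrink, but its larger error means that clock state is not excluded as its cause. More blood in the CS lungs would raise erythroid genes, and these were lower (-0.722 ± 0.259 over 8 genes), although with the clock components they stood at 0.430 ± 0.458. An influx of neutrophils with smoke is 1 hypothesis for the change, drawn from the same data, and it was not tested. Smoke need not be the only influence, since the list was also higher in RA_Los than in RA (median 0.377; adjusted p = 0.00175; adjusted p = 0.345 with an estimated correlation), and the mean on RA_Los 2 (8.27) was above that on CS 1 (8.25).

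A further question is why no gene was called between CS_Los and CS. If differing clock states hid a losartan effect, the clock components might uncover it, but 2 genes were called with them (Mrc2 and Ccl6), and with them CS against RA kept 0 of its 1631 calls. Leaving out any of the 6 arrays gave at most 0 calls. Yet the fit with all 6 recovered 65 of 100 simulated changes of 1 and 10 of 100 of 0.5, and this may be overstated for batch 1. Neither low count therefore excludes clock state or an outlying array. The smoke score moved with single CS_Los arrays, from -0.486 to -0.865 (fry p = 0.0205, exact permutation p = 0.1) without CS_Los 1 and to -0.109 without CS_Los 2, and was -0.0959 ± 0.0601 with the clock components. These explanations, a small effect of losartan and none all stay open.

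Other splits of the samples were refitted. For CS against RA, 1 of 100 splits of the 14 arrays, the real one, gave 1631 genes, and the highest other gave 383. Chance is therefore unlikely for that count, though not excluded. The other splits were drawn without regard to batch, while the real groups are balanced over the batches. The 6 arrays of each losartan comparison allow 10 splits, too few for a share under 0.05. The real and the highest other counts were 0 and 8 for CS_Los against CS (10 splits gave at least 0), 1 and 13 for RA_Los against RA (2 splits gave at least 1), 0 and 4 for CS_Los against RA_Los (10 splits), and 1 and 0 for CS_Los against RA (1 split). For the losartan by smoke interaction the real count was 0 and the highest other 85. A count of 0 is reached by all 100 draws whatever the values, so it cannot be tested this way. Some splits called more genes than the real one, such as this 85, and neither the cause nor what those splits share was tested.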
